A study of Mus musculus with 16 samples.

How the data were processed

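H3K27ac ChIP-seq libraries were made from male and female mouse astrocytes null for Nf1 and p53, treated with 0.05% DMSO or with 500 nM JQ1 for 24 h. The deposited files comprised 12 peak lists, 3 for each of the 4 groups of sex and treatment, and 3 tables of differential sites, 1 for each of the comparisons male against female under DMSO, JQ1 against DMSO in male cells and JQ1 against DMSO in female cells. Input libraries have no files of their own and were not analysed here.

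Peaks were called by the authors with MACS2 2.1.1.20160309, 1 ChIP library at a time against the input of its own group, at a q-value cutoff of 0.01, per the file headers. Reads had been aligned with Bowtie2 2.3.4.3 to mm10, per the submitters' processing notes. Each deposited peak list gives the fragment pileup at the summit as a signal scaled by MACS2 between ChIP and input, the fold enrichment over the local background as a ratio, and the −log10 of the p-value and q-value. The ChIP alignments are named as merged in the file headers, and what was merged is not stated. The deposited tables of differential sites have no header. From their values and the submitters' processing notes they were read as DiffBind 3.5 reports made with DESeq2, in which the authors list the log2 mean of normalized read counts per group (the log2 concentration), the log2 fold between groups, the p-value and the FDR. These tables hold only sites at an FDR of at most 0.05, so no value exists for a site that missed it. The lowest log2 concentration listed was -0.10 for female and -0.04 for male cells in the sex table, -0.29 for DMSO and -0.15 for JQ1 in the male table, and -0.31 for DMSO and -0.19 for JQ1 in the female table. For a site with a group at that lowest value both concentrations are given and no fold. The direction of each fold was checked against the peak lists. Among sites with a log2 fold of at least 1, 75.6% of the sex table, 72.0% of the male JQ1 table and 72.3% of the female JQ1 table had a peak in more libraries of the higher group, and 5, 1 and 3 sites had fewer.

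Total tags per ChIP library were 16.7 to 22.7 M and tags after duplicate removal 14.0 to 18.9 M, per the file headers. Libraries held 46936 to 61795 peaks covering 43.6 to 53.9 Mb, with a median width of 505 to 642 bp. Read length was 50 to 101 bp. The single input of each group held 10.5 M tags after duplicate removal for male DMSO and 12.9 M for male JQ1. It held 12.6 M for female DMSO and 10.6 M for female JQ1. In covered length a difference between inputs therefore cannot be told apart from a difference between groups. Peak lists hold no counts at regions without a peak, so a covered length of 0 is a value listed at 0 and not a measured absence.

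Gene positions came from a table of the GRCm38.p6 assembly, the assembly behind mm10, without strand. The planned windows around transcription start sites were therefore replaced by the gene span with 10 kb on either side, and promoters by the distance of at most 1 kb from either gene end. As a check of the build, 24.9% of gene ends lay within 250 bp of a region with a peak in all 12 libraries, against 4.92% after a shift of 100000 bp. For each of 21888 genes the length covered by peaks was summed per library. Of 526 distinct genes on the lists 525 matched the table.

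Pairs of libraries of a group were compared by the pileup of 20929 regions present in all 12 libraries. In each group 1 pair differed by no more than counting noise (median chi-square 0.290, 0.347, 0.403 and 0.341, against 0.455 from counting alone), and all other pairs differed by more (0.653 to 9.90). The mean chi-square of these pairs was 0.659, 0.797, 1.26 and 0.755 against 1 from counting, so that a part of the regions differed beyond counting noise between female DMSO 1 and 2. Each such pair (male DMSO 2 and 3, male JQ1 1 and 3, female DMSO 1 and 2, female JQ1 1 and 3) was averaged, which left 2 samples per group. The design written before the data were examined had used the 12 libraries as separate samples, and the choice to average was made after seeing the data. The labels do not say whether replicates are separate cultures, so p-values measure the spread between samples only.

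Covered length was tested with limma 3.58.1 (R 4.3.3) on log2(covered length + 500 bp), with trend and robust fits across all 8 samples and Benjamini-Hochberg adjustment. The 15085 genes with covered length above 0 in at least 3 libraries entered. Fold changes are on this scale, which understates changes at small covered lengths, and no fold is given against a group listed at 0. Such a group shows no spread between its samples, so limma p-values against it may be too small. On simulated data for JQ1 in male cells with 15085 genes, 74.6% of genes changed by a log2 of 1, 97.0% at a log2 of 2 and 98.5% at a log2 of 3 were recovered, with 11 false calls, and an unchanged comparison gave 0. Peaks per sample were compared by an exact two-sided permutation test, whose smallest possible p with 2 samples per group is 0.333.

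Peaks of all libraries were merged into 81164 regions wherever they overlapped by at least 1 bp. The 63461 regions with a peak in at least 2 libraries served as the background for sites, a choice made after seeing the data. Each of the authors' sites was assigned to the nearest gene within 100 kb. Only protein-coding and listed genes were considered, so a site in another non-coding gene went to the nearest of these. Across the 27 gene lists, fixed before the data were examined, the members with a site were compared with 10000 random lists, a permutation of genes with matching numbers of regions, two-sided, with a smallest possible p of 0.0002 and adjustment over 54 tests per comparison. As a check, a single random draw among 13834 genes, weighted by their number of regions, gave 0 false lists. Marking every HOX gene as changed in that draw recovered the list. The draw used no site of any comparison, so it does not measure false calls among sites near gene ends. On covered length the lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, a rotation test of limma. Locations and overlaps were tested with Fisher's exact test, two-sided, with adjustment within each comparison. Sites and regions are not independent replicates. For comparisons that share DMSO samples, unchanged groups were simulated around the shared samples.

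Named genes followed a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls in covered length at an adjusted p under 0.05 with groups that do not overlap, the 6 largest positive and 6 largest negative folds of the authors' sites within 50 kb of a gene, and up to 4 members of each described list with the lowest FDR. Genes known only by a clone or model number were passed over. It always took Xist, Ddx3y, Uty, Kdm5d, Eif2s3y, Nf1, Trp53, Brd4, Hexim1 and Myc. Alternatives covered the margin around genes, the pseudocount, the filter on covered length, stricter peaks, equal numbers of peaks, scaling by total covered length, the fit, the FDR and leaving out each sample. The fit of 12 separate libraries, a block for the sample with fewer peaks, all regions as background and the stricter FDR for locations were added after seeing the data. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.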

Results

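H3K27ac, a histone mark of active promoters and enhancers, was mapped in mouse astrocytes that lack Nf1 and p53 and serve as a model of glioblastoma. The libraries covered male and female cells under DMSO, the solvent, and under 500 nM JQ1, which displaces BET proteins such as BRD4 from acetylated chromatin, for 24 h. Each of the 4 groups held 3 ChIP libraries of 16.7 to 22.7 M tags, which formed 2 samples per group after libraries alike within counting noise by their median were averaged. Group means were 50414 ± 4650 peaks in male DMSO cells, 53292 ± 8632 in male JQ1 cells, 52386 ± 1828 in female DMSO cells and 50946 ± 1964 in female JQ1 cells (SD, n = 2). Exact permutation tests of these numbers gave p = 1 for sex, 0.667 for JQ1 in male cells and 0.667 for JQ1 in female cells, where 0.333 is the smallest p possible. The labels name a single male and a single female line, so sex and cell line cannot be told apart in any comparison. Peaks of each group were called against a single input of its own, so input and group cannot be told apart either. All coordinates are mm10.

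The first comparison asked how H3K27ac differs between male and female cells under DMSO. Several homeobox genes of brain patterning differed between the lines. Peaks covered 14.6 ± 0.0124 kb around Nkx2-1, a ventral forebrain regulator (chromosome 12, 56531935 to 56536908), in male cells, while the gene was listed at 0 in every female sample (n = 2 per group, limma adjusted p = 3.95e-06). Vax1, a homeobox gene of the ventral forebrain and optic stalk, had 8.35 ± 0.411 kb in male cells and Otx2, a forebrain and midbrain regulator, 6.02 ± 0.238 kb, both listed at 0 in female cells (limma adjusted p = 9.97e-06 for each). Lmx1b, a homeobox gene of the midbrain-hindbrain boundary and dorsal spinal cord, went the other way with 7.38 ± 0.221 kb in female cells and 0 in male cells (limma adjusted p = 1.22e-05). Adam19, a membrane metalloprotease, had 17.0 ± 1.27 kb in female and 0.359 ± 0.507 kb in male cells, a log2 difference of -4.48 ± 0.37 (SE, limma adjusted p = 0.00214).

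Y-linked genes and Xist followed the sex labels. Covered length around the Y-linked genes Ddx3y (0.958 ± 0.142 kb), Uty (0.616 ± 0.226 kb), Eif2s3y (0.753 ± 0.355 kb) and Kdm5d (0.397 ± 0.0205 kb) was present in all male samples and listed at 0 in all female samples, with limma adjusted p of 0.00722, 0.0392, 0.0204 and 0.0614. Kdm5d did not pass. Xist, the RNA that silences an X chromosome, had 2.27 ± 0.106 kb in female and 0.717 ± 0.238 kb in male cells (log2 -1.20 ± 0.19 SE, n = 2, limma adjusted p = 0.0169). With 1 sample fewer these genes often missed the threshold. The limma adjusted p was 0.205 for Uty, 0.0654 for Ddx3y and 0.0990 for Eif2s3y without male DMSO 1, and 0.0718 for Uty and 0.0691 for Xist without male DMSO 2 and 3. Without female DMSO 1 and 2 it was 0.181 for Uty, 0.0661 for Ddx3y, 0.125 for Eif2s3y and 0.123 for Xist, and without female DMSO 3 0.169, 0.0586, 0.112 and 0.0972. In the authors' deposited table the Xist site (X chromosome, 103481796 to 103482396) had a log2 concentration of 8.34 in female and 1.18 in male cells (log2 fold -7.16, FDR = 2e-43). Other genes with large male-higher covered length were the keratin genes Krt81 and Krt88, whose windows share the same peaks (7.03 ± 0.801 against 0.539 ± 0.151 kb, log2 2.86, limma adjusted p = 0.000347), and Crabp1, a retinoic acid binding protein gene (3.15 ± 0.788 kb against 0, limma adjusted p = 0.00308). Female-higher genes were Nkain4 (11.8 ± 1.23 against 0.134 ± 0.189 kb, log2 -4.31), Crocc2 (8.41 ± 0.942 against 0.0645 ± 0.0912 kb, log2 -3.98), Vit (7.61 ± 1.46 kb against 0) and Dkk2, a WNT modulator (7.28 ± 1.51 kb against 0), with limma adjusted p of 0.00102, 0.0015, 0.000257 and 0.003.

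**Figure D1:**
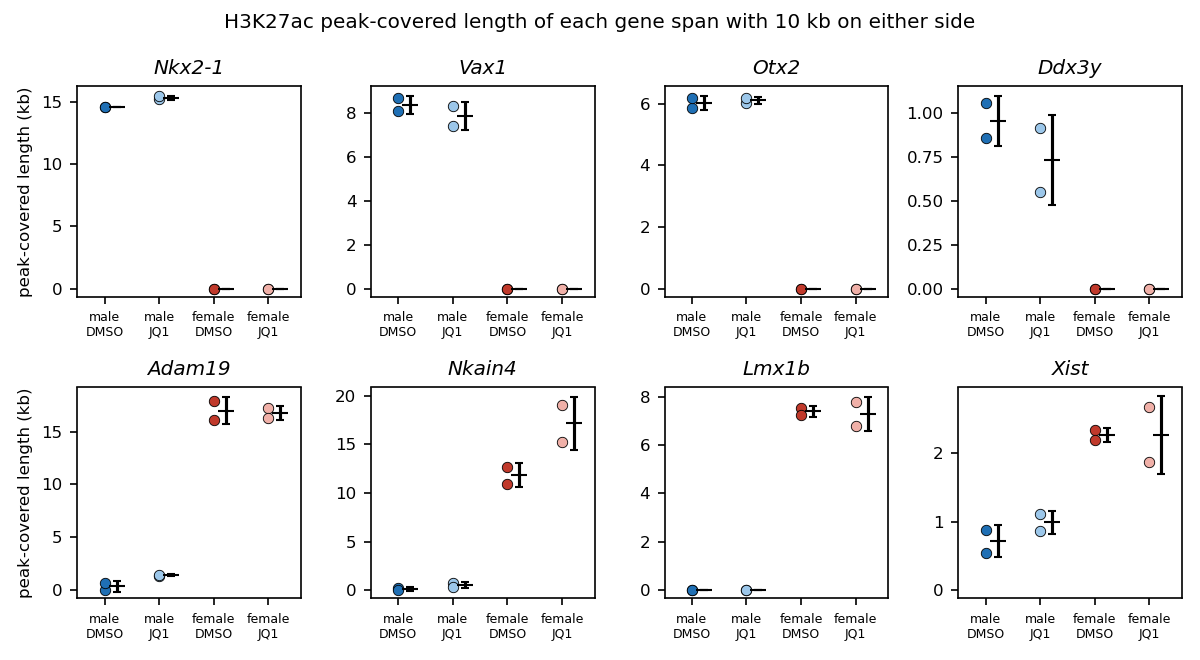
Peak-covered length in kb (vertical axis) of 8 gene spans with 10 kb on either side, per sample, with the mean and SD (n = 2) beside the points, for male and female cells under DMSO and JQ1. Nkx2-1, Vax1, Otx2 and Ddx3y were listed at 0 in all female samples and Lmx1b in all male samples.

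Over all 15085 genes, 344 had more and 1012 less covered length in male than in female cells (limma, adjusted p under 0.05). Scaling each sample by its total covered length gave 508 and 730, so that 41.0% in place of 25.4% of the calls were male-higher. The 12 libraries taken as separate samples gave 869 and 2634 calls, and without 1 sample the total was 283 (female DMSO 1 and 2 left out), 345 (female DMSO 3), 419 (male DMSO 1) or 701 (male DMSO 2 and 3). Regions with a peak in all 3 libraries of a sex and in none of the other numbered 2469 for male and 4499 for female cells. The authors' deposited table listed 24377 sites near 7303 genes, 12259 male-higher and 12118 female-higher. Of these, a site near Nkx2-1 (chromosome 12, 56520558 to 56521158) had a log2 concentration of 8.54 in male cells and the lowest listed value in female cells, -0.10 (FDR = 1.18e-39). A site in Dhh, which encodes a hedgehog ligand (chromosome 15, 98895631 to 98896231), was male-higher by a log2 fold of 7.15 and a site near Scube3 (chromosome 17, 28123507 to 28124107) by 6.79. A site near Tbx18, a T-box gene of mural cells (chromosome 9, 87739423 to 87740023), had 8.72 in female cells and the lowest listed value in male cells, -0.04 (FDR = 2.97e-42). Sites in Prdm6 (8.16) and Lrrc8d (7.86) and near Zfhx4 (8.07) also had that lowest male value, and a site in Clmp (chromosome 9, 40686051 to 40686651) was female-higher by a log2 fold of -7.72.

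Of the patterning lists, HOX genes passed by covered length and none passed on the authors' sites. All 5 HOX genes of the list, which mark the hindbrain and trunk, passed as lower in male cells by covered length (5 adjusted over the list alone), and camera gave an adjusted p of 6.51e-07 for the list. Windows of neighbouring genes such as Hoxb2 and Hoxb3 may share peaks, so these 5 genes may not be independent. With an estimated correlation, under which camera called 0 lists, the HOX list had an adjusted p = 0.445 and the Y-linked list, at 9.89e-06 with the preset one, an adjusted p = 0.233. Of 5 HOX genes, 4 had a female-higher site in the authors' deposited table against 1.72 in random lists (adjusted p = 0.580). Among them were Hoxa1 (6.88 in female cells), Hoxb3 (6.67) and Hoxb2 (6.47), each at the lowest listed male log2 concentration of -0.04. Of 20 genes of midbrain, hindbrain and dorsal patterning, 14 had a female-higher site against 8.24 in random lists (permutation p = 0.0096, adjusted p = 0.259), and 7 had a male-higher one. Sites near Msx1 (log2 fold -6.89), in Lmx1b (-6.55) and in Pax2 (-2.39) were female-higher, and a site in Irx2 (2.61) was male-higher. By covered length 1 gene of this list passed as male-higher and 5 as female-higher (2 and 7 adjusted over the list alone, camera adjusted p = 0.0544). Forebrain patterning genes went both ways, with 11 of 17 holding a male-higher and 10 a female-higher site (adjusted p = 1 for both), and with 3 genes higher and 5 lower in male cells by covered length (5 and 5 adjusted over the list alone). The forebrain sites with the lowest FDR were male-higher, in Otx2 (log2 fold 6.49) and Six3 (3.27) and near Dlx2 (3.12).

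**Figure D2:**
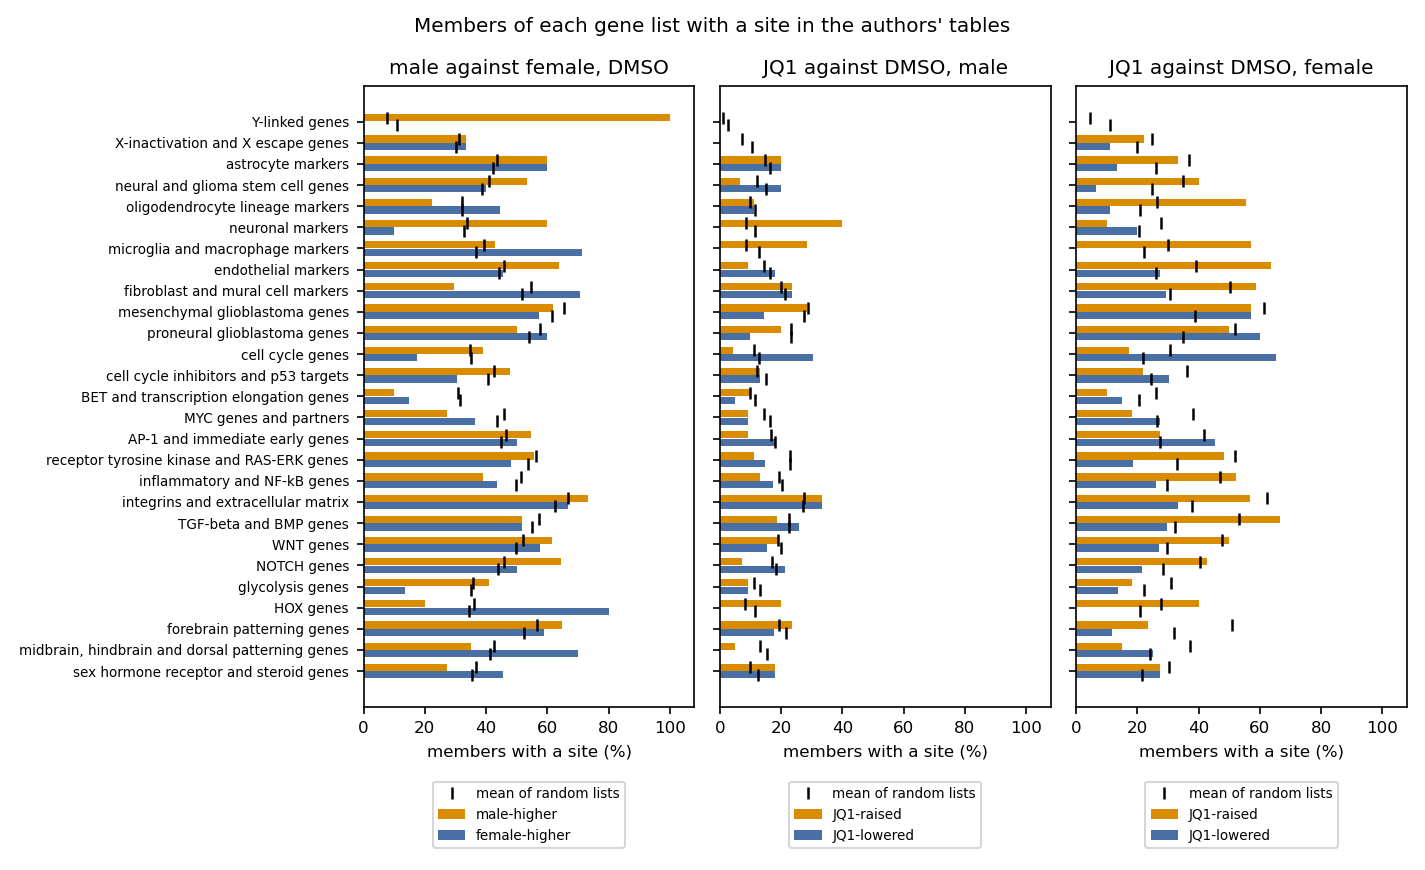
Percent of the members of each of the 27 gene lists (vertical axis) with at least 1 site in the authors' deposited tables, by direction, with the mean of 10000 random lists as a black mark. All 4 Y-linked genes had a male-higher site, and 15 of 23 cell cycle genes had a JQ1-lowered site in female cells.

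On the authors' sites, of 27 lists only the Y-linked one passed in the sex comparison (4 of 4 with a male-higher site against 0.305 in random lists, permutation p = 0.0002, the smallest possible, adjusted p = 0.0108). On covered length camera called the Y-linked and HOX lists, while fry called 13 of 27 lists, and 4 after scaling by total covered length. With an estimated correlation both camera calls were lost (adjusted p = 0.233 and 0.445). Fry called 21 lists with a block by the sample with fewer peaks and 24 with 12 separate libraries. The 13 included markers of astrocytes, oligodendrocytes, microglia and fibroblasts (limma fry adjusted p = 0.0457, 0.0133, 0.00526 and 0.0124) and the forebrain and midbrain patterning lists (0.00101 for each). Of 17 fibroblast and mural cell markers, 12 had a female-higher site against 8.80 (adjusted p = 0.661) and 5 a male-higher site against 9.28 (adjusted p = 0.382). Female-higher sites of this list included those near or in Foxc1 (log2 fold -7.45), Rgs5 (-5.98) and Tbx15 (-2.71). Astrocyte markers split evenly, with 9 of 15 holding a male-higher and 9 a female-higher site. Gja1 (-3.77), Nfia (-4.92) and Nfib (-1.30) were female-higher and Slc1a3, an astrocytic glutamate transporter gene on chromosome 15, male-higher (2.50). X-inactivation and escape genes had male-higher sites at 3 of 9 members, such as Ddx3x (1.25), and female-higher sites at 3, such as Ftx (-2.32). Of 20 BET and elongation genes, 2 had a male-higher site against 6.19 in random lists (adjusted p = 0.319) and 3 a female-higher one, in Aff1 (-1.58) and near Hexim2 (-1.77) and Mllt3 (-3.58). Covered length did not pass for Nf1 (4.64 ± 0.568 in male, 4.08 ± 0.948 kb in female cells), Trp53 (3.52 ± 0.0693, 4.39 ± 0.335), Brd4 (1.75 ± 0.0382, 1.90 ± 0.0343), Hexim1 (3.72 ± 0.296, 3.28 ± 0.0184) or Myc (7.13 ± 0.977, 7.65 ± 1.25), with limma adjusted p of 0.612, 0.367, 0.574, 0.34 and 0.809 (n = 2). Brd4, Hexim1 and Trp53 had no site in any of the authors' deposited tables. Nf1 had 4 sites, 3 of them male-higher, and Myc 11, 10 of them male-higher.

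The share of male-higher sites differed by chromosome. On chromosome 15, which carries Myc, Krt81, Krt88 and Dhh, 75.4% of 1487 sites were male-higher (Fisher's exact adjusted p = 2.31e-91), and on chromosome 16 31.2% of 905 sites (2.86e-31). In all, 18 of 20 chromosomes departed from the rest. Sites within 1 kb of a gene end made up 8.21% of male-higher and 8.07% of female-higher sites (odds ratio 1.02, Fisher's exact adjusted p = 0.691).

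**Figure D3:**
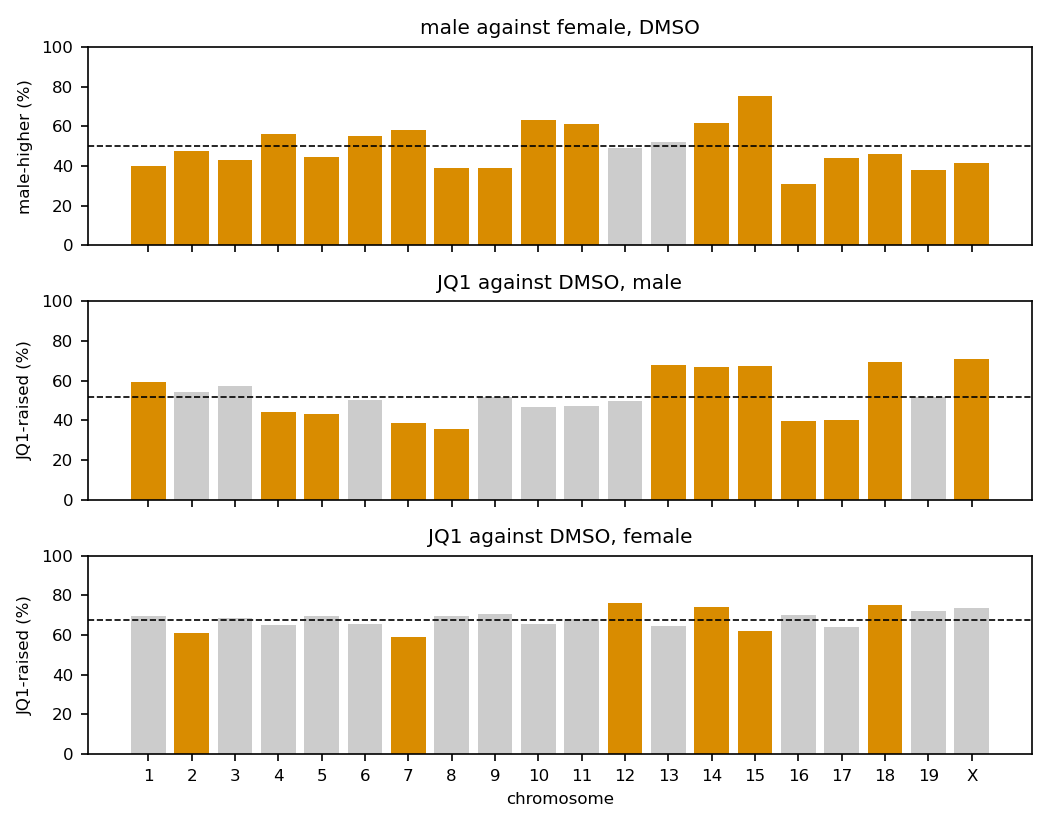
Percent of the authors' sites on each chromosome that were male-higher (top) or raised by JQ1 in male (middle) and female cells (bottom), with orange bars for chromosomes that passed Fisher's exact test and a dashed line for the whole table. Chromosome 15 had 75.4% and chromosome 16 31.2% male-higher sites.

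The second comparison asked what JQ1 does to H3K27ac in male cells. Bmp6, a bone morphogenetic protein gene, rose from 0.326 ± 0.00707 to 3.90 ± 1.63 kb (log2 2.36 ± 0.24 SE, n = 2, limma adjusted p = 0.0321). Haao, an enzyme gene of tryptophan breakdown, fell from 2.1 ± 0.203 to 0.116 ± 0.163 kb (log2 -2.1 ± 0.22 SE, limma adjusted p = 0.0321), and Spon2, a secreted matrix protein gene, from 1.70 ± 0.144 to 0.120 ± 0.170 kb (log2 -1.85 ± 0.22 SE, limma adjusted p = 0.0374). Col22a1, a collagen gene, was listed at 0 under DMSO and had 2.02 ± 0.103 kb under JQ1 (limma adjusted p = 0.0285).

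Rec114 (2.41 ± 0.839 kb), Syt2, a synaptotagmin gene (1.64 ± 0.286 kb), Pex5l (1.52 ± 0.686 kb) and Krt39 (1.45 ± 0.116 kb) were also listed at 0 under DMSO and rose under JQ1, with limma adjusted p of 0.0321, 0.0285, 0.0378 and 0.0285. Fam163a (1.93 ± 0.226 to 0.204 ± 0.289 kb), Jph2 (1.22 ± 0.271 to 0.0602 ± 0.0852 kb) and Tmem204 (1.16 ± 0.129 to 0.0520 ± 0.0735 kb) fell by 1.85, 1.61 and 1.59 on the log2 scale (limma adjusted p = 0.0488, 0.0354 and 0.0285). Krt7 went from 1.10 ± 0.4 kb to 0 (limma adjusted p = 0.0404). In all, 58 genes gained and 56 lost covered length (limma, adjusted p under 0.05), or 69 and 122 with equal numbers of strongest peaks. This count fell to 0 without male DMSO 1, without male DMSO 2 and 3 or without male JQ1 2 (limma, 1771, 2110 and 2374 genes at an unadjusted p under 0.05), was 521 without male JQ1 1 and 3, and was 1906 with the 12 libraries as separate samples. A block by the sample with fewer peaks gave 995 genes, and fitting only the compared groups gave 0 (limma, 1643 at an unadjusted p under 0.05). Nf1 (4.64 ± 0.568 to 3.23 ± 0.352 kb), Trp53 (3.52 ± 0.0693 to 3.73 ± 0.828), Brd4 (1.75 ± 0.0382 to 1.74 ± 0.145), Hexim1, a marker of BET inhibition (3.72 ± 0.296 to 3.08 ± 0.0269), and Myc (7.13 ± 0.977 to 8.97 ± 0.294) did not pass, with limma adjusted p of 0.277, 0.912, 0.989, 0.248 and 0.454 (n = 2). Neither did Xist (0.510), Ddx3y (0.591), Uty (1), Kdm5d (0.759) or Eif2s3y (0.666), given as limma adjusted p.

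The authors' deposited table listed 4967 sites near 2749 genes, 2561 raised and 2406 lowered. A site in Creb5, a bZIP transcription factor gene (chromosome 6, 53506313 to 53506913), had the lowest listed log2 concentration under DMSO, -0.29, and 7.02 under JQ1 (FDR = 4.69e-22). A site near Neto2 (chromosome 8, 85602090 to 85602690) went from 7.19 to the lowest listed JQ1 value, -0.15 (FDR = 2.24e-23). All 4 sites assigned to Myc, spread from 61999539 to 62054112 on chromosome 15, were raised. Among them was a site at 62043486 to 62044086 (log2 fold 1.10, FDR = 0.0114). The only Nf1 site (chromosome 11, 79414032 to 79414632) was lowered by a log2 fold of -2.1 (FDR = 0.0193).

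Neuronal markers and cell cycle genes had the lowest unadjusted p among gene lists tested on the authors' sites against random lists, and neither passed. The random lists called 0 of 27 lists, with 2 at an unadjusted p under 0.05, and Fisher's exact test without matching called 2. Of 10 neuronal markers 4 had a raised site against 0.872 in random lists (permutation p = 0.0082, adjusted p = 0.443), namely Stmn2 (log2 fold 3.61), Elavl4 (2.68), Gad2 (1.66) and Map2 (1.49). Of 23 cell cycle genes 7 had a lowered site against 2.97 (permutation p = 0.0348, adjusted p = 0.940), such as Cdc25a (-1.94), E2f1 (-1.59) and Mcm5 (-1.18), while Cdk6 had a raised one (3.25). TGF-beta and BMP genes had raised sites at 5 and lowered sites at 7 of 27 members (adjusted p = 1 for both), raised near Nog, a BMP antagonist gene (3.09), and in Bmp6 (2.02) and lowered near Grem1 (-2.78). Of 22 AP-1 and immediate early genes 2 had a raised and 4 a lowered site. Klf6 (3.54) was raised, Ier5 (-1.59) and Egr1 (-2.06) were lowered, and a site near Fos went from the lowest listed DMSO value, -0.29, to 4.89. MYC genes and partners had a raised site at 1 and a lowered site at 1 of 11 members, Myc and Mxd1. Of 20 BET and elongation genes 2 had a raised and 1 a lowered site, in Mllt1 (1.98) and Med1 (-2.45) among others. On covered length camera and fry each called 0 of 27 lists, and camera had 0 at an unadjusted p under 0.05 (1 list called without male DMSO 1). Lowered sites lay within 1 kb of a gene end more often (9.39%) than raised ones (2.66%, Fisher's exact adjusted p = 2.38e-23).

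The third comparison asked the same of female cells. Wnt7b, a WNT ligand gene, rose from 0.167 ± 0.235 to 3.01 ± 0.384 kb (log2 2.44 ± 0.34 SE, n = 2, limma adjusted p = 0.0438). Adamts16, a secreted protease gene, rose from 0.0633 ± 0.0895 to 2.94 ± 0.187 kb (log2 2.62 ± 0.32 SE, limma adjusted p = 0.0361). Grem1, which encodes a BMP antagonist, fell from 1.99 ± 0.0711 to 0.206 ± 0.292 kb (log2 -1.88 ± 0.26 SE, limma adjusted p = 0.0438), and Ido1, an enzyme gene of tryptophan breakdown, from 1.43 ± 0.0732 to 0.0777 ± 0.110 kb (log2 -1.75 ± 0.19 SE, limma adjusted p = 0.0351).

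Fam167a (2.12 ± 0.629 to 13.6 ± 0.0757 kb), Lypd2 (0.621 ± 0.151 to 5.41 ± 0.0099 kb) and Syt2 (0.445 ± 0.206 to 2.84 ± 0.209 kb) rose by log2 values of 2.45, 2.41 and 1.84 (limma adjusted p = 0.0328, 0.0334 and 0.0334), and Vwa2 went from 0 to 2.31 ± 0.534 kb (0.0328). Rtn2 (2.25 ± 0.485 to 0.207 ± 0.111 kb), Sh3gl3 (2.49 ± 0.248 to 0.283 ± 0.128 kb) and Rmi2, a DNA repair gene (3.27 ± 0.149 to 0.640 ± 0.0544 kb), fell by 1.95, 1.94 and 1.73 on the log2 scale (limma adjusted p = 0.0365, 0.0328 and 0.0351), and Acox2 went from 1.26 ± 0.0343 kb to 0 (0.0334). In all, 56 genes gained and 87 lost covered length (limma, adjusted p under 0.05), or 56 and 37 after scaling by total covered length, which moved the share of gains from 39.2% to 60.2%. The count fell to 0 whichever of the 4 samples was left out (female DMSO 1 and 2, female DMSO 3, female JQ1 1 and 3, female JQ1 2), with limma giving 1584, 1872, 1867 and 1798 genes at an unadjusted p under 0.05, and was 2347 with the 12 libraries as separate samples. The same block gave 960 genes, and fitting only the compared groups 0 (limma, 3365 at an unadjusted p under 0.05). Nf1 (4.08 ± 0.948 to 3.04 ± 0.450 kb), Trp53 (4.39 ± 0.335 to 3.6 ± 0.602), Brd4 (1.90 ± 0.0343 to 1.81 ± 0.0576), Hexim1 (3.28 ± 0.0184 to 3.24 ± 0.133), Myc (7.65 ± 1.25 to 7.15 ± 1.54) and Xist (2.27 ± 0.106 to 2.27 ± 0.571) did not pass, with limma adjusted p of 0.366, 0.471, 0.797, 0.955, 0.838 and 0.996 (n = 2).

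The authors' deposited table listed 13670 sites near 5770 genes, of which 9228 (67.5%) were raised and 4442 lowered. Sites near Elobl (chromosome 11, 88969792 to 88970392) and in Cntnap2, a neuronal adhesion gene (chromosome 6, 46729719 to 46730319), rose from the lowest listed DMSO value, -0.31, to log2 concentrations of 6.48 and 6.23. A site in Ccdc12 (chromosome 9, 110669393 to 110670554) was raised by a log2 fold of 6.05 (FDR = 1.6e-25). Sites in Reps1 (chromosome 10, 18080824 to 18081424) and near Ido2, the neighbour of Ido1 (chromosome 8, 24579279 to 24579879), were lowered by log2 folds of -5.60 and -5.35. All 8 sites assigned to Myc, spread from 61974361 to 62079115 on chromosome 15, were raised. Their log2 folds reached 3.66 at 62054148 to 62054748, while covered length within 10 kb of Myc did not pass. The Nf1 site at chromosome 11, 79414032 to 79414632 was lowered as in male cells (-1.18, FDR = 0.00309).

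Cell cycle genes were the single list that passed on these sites. Of 23 members, 15 had a lowered site against 5.03 in random lists (permutation p = 0.0002, the smallest possible, adjusted p = 0.0108), and 4 had a raised one. Sites in the cyclin genes Ccna2 (log2 fold -1.11) and Ccne2 (-1.0) were lowered, and sites near Cdc25a (2.17) and Cdk6 (2.50) raised. The list no longer passed at an FDR of 0.01, the random lists were not matched on distance to gene ends, and by covered length 0 members passed over all genes (1 gain adjusted over the list alone, camera adjusted p = 0.640). Camera and fry each called 0 of 27 lists, with 2 at an unadjusted camera p under 0.05 and 1 list called by camera without female DMSO 3. Fry called 4 lists with a block by the sample with fewer peaks and 9 with 12 separate libraries. TGF-beta and BMP genes had a raised site at 18 of 27 members against 14.3 (adjusted p = 0.555), among them the receptor genes Tgfbr3 (3.66), Tgfbr1 (2.37) and Tgfbr2 (1.39) and Nog (2.49). Of 22 AP-1 and immediate early genes 10 had a lowered site against 6.02 (adjusted p = 0.555), such as Ier5 (-1.60) and Egr1 (-1.06), and 6 a raised one, such as Fos (1.43) and Ier3 (2.01). MYC genes and partners had a raised site at 2 and a lowered site at 3 of 11 members, lowered in Mlxip (-1.29) and near Mxd3 (-0.86). BET and elongation genes had a raised site at 2 and a lowered site at 3 of 20 members, raised near Mllt3 (2.36) and lowered in Hexim2 (-1.10). Of 4442 lowered sites 26.4% lay within 1 kb of a gene end, against 5.91% of raised sites (Fisher's exact adjusted p = 1.1e-232).

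The fourth comparison asked whether the JQ1 response differs between the sexes. Limma called 0 of 15085 genes for the difference of the responses, with 1452 genes at an unadjusted p under 0.05, and every gene named for covered length had an adjusted p of at least 0.144 in that test. With the 12 libraries as separate samples 670 genes were called. Among the authors' sites, 1117 regions were raised in both sexes against 372 for independent lists, and 734 were lowered in both against 168 (Fisher's exact adjusted p = 9.77e-290 and 1.37e-277). These tables share no library. Of 1941 sites listed in both, 95.4% had the same direction, 23 were raised in male and lowered in female cells, and 67 the reverse. Sites near Nog (chromosome 11, 89206688 to 89207288) and Ier5 (chromosome 1, 155055803 to 155056403) changed alike in male (3.09 and -1.59) and female cells (2.49 and -1.60).

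The fifth comparison asked whether regions that differ between the sexes are those that JQ1 changes. In male cells, JQ1 lowered 954 male-higher regions against 465 for independent lists and raised 832 female-higher regions against 489, while it raised 220 male-higher regions against 495 (Fisher's exact adjusted p = 3.59e-122, 1.08e-60 and 1.03e-52). The same site near Fos (chromosome 12, 85462633 to 85463233) was in both tables, female-higher with a log2 concentration of 6.64 against the lowest listed male value, -0.04, and raised by JQ1 in male cells from the lowest listed DMSO value, -0.29, to 4.89. A site near Myc (chromosome 15, 61999539 to 62000139) did likewise, from 5.41 in female against -0.04 in male cells, and from -0.29 to 4.15 under JQ1, again at the lowest listed values. Another site assigned to Myc (chromosome 15, 62053512 to 62054112) was male-higher (1.80) and raised by JQ1 in male cells (1.34). Of 11 sites assigned to Myc, 10 were male-higher. Both changes were measured from the same male DMSO samples, which by itself links them. Across genes, their covariance was -0.0541 against -0.0206 in simulated unchanged groups, and -0.0548 and -0.0359 when each change took its own male DMSO sample. Their correlation across genes, which are not independent replicates, was -0.30 against -0.50 simulated. In female cells JQ1 raised 2634 female-higher regions against 1762 for independent lists and lowered 896 against 848, and it raised 1642 male-higher regions against 1782 and lowered 793 against 858 (Fisher's exact adjusted p = 3.62e-126, 0.0574, 7.32e-05 and 0.0120). In these cells the covariance was 0.00227 against 0.0205 simulated around the shared female DMSO samples.

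**Figure D4:**
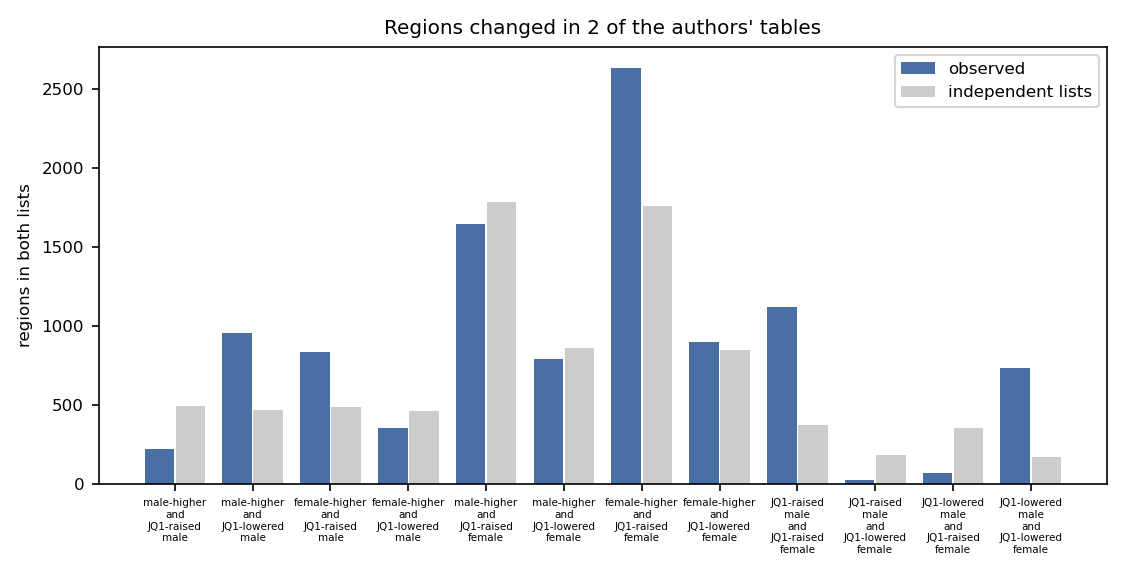
Number of regions (vertical axis) changed in 2 of the authors' deposited tables, for 12 pairs of directions, beside the number for independent lists of the same sizes. JQ1-raised regions of male and female cells shared 1117 regions against 372.

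Under JQ1 the sex difference persisted at Nkx2-1 and Lmx1b. Nkx2-1 had 15.3 ± 0.169 kb in male cells and 0 in female cells, and Lmx1b 7.28 ± 0.698 kb in female cells and 0 in male cells (n = 2, limma adjusted p = 3.62e-06 and 1.05e-05). In all, 629 genes had more and 1253 less covered length in male than in female cells under JQ1 (limma, adjusted p under 0.05). Of the 344 genes higher in male cells under DMSO 231 were called again (67.2%, against 14.3 genes for independent lists), and of the 1012 higher in female cells 623 (61.6%, against 84.1), while 7 genes were called in opposite directions. Both comparisons came from the same fit, with a shared variance estimate per gene. That by itself favours genes called in both, so independent lists understate the overlap to be had without a lasting difference. The count under JQ1 was 460 without female JQ1 1 and 3, 533 without female JQ1 2 and 378 when only these groups were fitted.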

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

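All tests in this part were chosen after the results they measure had been seen, except the test of the strongest sites for chromosome copy number and the test of total covered length.

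Some patterning genes differed between the lines, with male-higher sites at Nkx2-1 and Otx2 and female-higher sites at HOX genes and Lmx1b, although no patterning list passed on the authors' sites. A wrong sex label is argued against by the Y chromosome, since 6 of 6 male libraries had peaks at all 4 male-specific genes and 0 female libraries had one. Fibroblast or mural cells mixed into the female cells cannot be told apart from a difference between the lines: 12 of 17 markers had female-higher sites against 8.80 in random lists (permutation adjusted p = 0.661) and limma's fry, though not its camera, called the list lower in male cells (adjusted p = 0.0124 and 0.428), while 2 of 3 abundant collagen genes had male-higher sites only (5 at Col1a1, 8 at Col1a2 and 4 female-higher at Col3a1), and the wide cover of Col1a1 in both sexes (27.2 and 26.1 kb) would hide a small share of such cells. Different regions of origin of the male and female cultures may underlie the pattern: 10 of 20 midbrain, hindbrain and dorsal genes had female-higher sites only and 3 male-higher sites only. Forebrain genes did not follow such a division (male-higher sites at 11 of 17, female-higher at 10; 3 higher and 5 lower in male cells by covered length), and region of origin and sex cannot be told apart, because the labels give a single line of each sex.

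Chromosome 15 held the highest share of male-higher sites, and Myc and Krt81 lie on it. A copy number of chromosome 15 that differs between the lines is a candidate explanation, because 94.1% of its 489 strongest sites (above the 75 percent quantile of concentration) were male-higher, against 71.6% of 6106 strongest sites over all chromosomes and 42.4% to 83.0% on the others. The size of the shift is weaker evidence, with a median log2 fold of 0.91 for these sites against 0.70 over all chromosomes and 0.82 on chromosome 14, and in the window from 10 to 20 Mb 28.1% of 121 sites were male-higher (median log2 fold -3.16). Within the male line JQ1 raised 67.6% of 275 sites on chromosome 15 against 50.6% elsewhere (Fisher's exact adjusted p = 2.57e-07). This was not particular to chromosome 15. In male cells 12 of 20 chromosomes departed from the rest, and chromosomes X (70.8%), 18 (69.6%) and 13 (68.0%) had higher raised shares. In female cells the share on chromosome 15 was lower than elsewhere, at 61.9% against 67.8% (Fisher's exact adjusted p = 0.00654). A copy number that differs between the lines predicts no shift under JQ1, so these shares do not decide on it. A few stretches of the chromosome are argued against, since 81.8% of its windows of 10 Mb (9 of 11) had over 60% male-higher sites. A sex difference in regulation along this chromosome was not tested and stays open.

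Of 12256 male-higher regions JQ1 lowered 954 in male cells, against 465 for independent lists, and raised 220, and of 12115 female-higher regions it raised 832, against 489, and lowered 356. Shared male DMSO samples were tested on covered length per gene, another measure than these regions. There the covariance of both changes stayed below 0 when each took its own DMSO sample, at -0.0359 and -0.0548 (SE over chromosomes 0.0036 and 0.00428). For covered length this argues against noise of a single shared sample as the whole link. Deviations common to the male DMSO samples, which have the same input, would remain. No value for unchanged groups was computed for the overlap of regions, so its excess stays unexplained. Scaling by total covered length gave -0.0402 and -0.0574. Such scaling shifts all genes of a library by nearly the same log2 amount, which a covariance across genes removes. This test therefore cannot decide on total covered length. A biological explanation was not tested and stays open. For JQ1 in female cells the same covariances were -0.00712 and -0.00530 (SE over chromosomes 0.0023 and 0.00234), with correlations of -0.0365 and -0.0308. Noise of the shared female DMSO samples would by itself make the covariance positive (0.0205 simulated).

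The authors' deposited tables listed some sites in opposite directions in the sexes, and these differences were not tested. A site near Hes1 (chromosome 16, 30080431 to 30081031) had a JQ1 log2 fold of -3.26 in male and 1.51 in female cells. A site in Nfkb1 (chromosome 3, 135623237 to 135623837) went from a log2 concentration of 3.32 to the lowest listed JQ1 value, -0.15, in male cells and had a log2 fold of 2.20 in female cells. A site in Rbpj (chromosome 5, 53564376 to 53564976) had -1.41 in male and 0.47 in female cells. On the Y chromosome, 15 peaks were listed in 5 of 6 female libraries. All 15 lay beyond 90 Mb, away from the 4 male-specific genes, and 2 male libraries had 4 peaks there.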

How the results depend on the processing

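The fit of 12 separate libraries, alone or split at random, and the block by the sample with fewer peaks were chosen after the results had been seen. Direction was checked only for the named largest rises and falls and the genes always named. Those past the threshold had groups that do not overlap, so leaving out a sample or changing the pseudocount could not reverse their sign. Nkx2-1, Lmx1b and the other such genes past the threshold kept their direction under the remaining alternatives too. They stayed past it in 216 of 224 values for sex, 133 of 166 for JQ1 in male cells and 131 of 167 for JQ1 in female cells, and, without 1 sample, in 51 of 64, 12 of 48 and 0 of 48.

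Numbers of genes with changed covered length moved most with the samples. Taking 12 libraries as separate samples gave 3503 genes for sex, 1906 and 2347 for JQ1 in male and female cells, 670 for the difference of responses and 4153 for sex under JQ1, and adding a replicate block 3669, 2047, 2421, 588 and 4334. Libraries alike within counting noise are then counted separately. A block by the sample with fewer peaks gave 2605, 995, 960 and 3365 (difference of responses 0). A margin of 50 kb gave 2272 for sex, 258 for JQ1 in male cells and 2974 for sex under JQ1, and a margin of 2 kb 86 for JQ1 in female cells. Fitting only the compared groups gave 871, 0, 0 and 378. Limma without trend and robust fits gave 189, 266 and 26 for both JQ1 comparisons and the difference of responses. Without the filter on covered length JQ1 in male cells gave 73 and the difference of responses 37. For JQ1 in male cells equal numbers of peaks gave 191, scaling by total covered length 177 and stricter peaks 68. For JQ1 in female cells scaling gave 93 and a pseudocount of 2000 bp 233. Leaving out a sample gave 283 to 701 for sex, 0 to 521 and 0 to 0 for JQ1 in male and female cells, 0 to 0 for the difference of responses and 460 to 1903 for sex under JQ1, with the lone sample assumed to vary like the others. Limma had 1584 to 3365 genes at an unadjusted p under 0.05 wherever it called 0 for JQ1 in male or female cells. The causes were not tested. Depth limits which weak peaks are listed, and equal numbers of peaks (46936 per library) gave 1257 genes for sex and 165 for JQ1 in female cells.

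Same-numbered libraries correlated above 0.1 in 11 of 18 pairs (-0.41 to 0.51), so the numbers do not pair the samples. The samples with fewer peaks correlated with each other across groups in 6 of 6 pairs (0.28 to 0.50). They were picked by peak number, a measure of the same peaks, which by itself favours a positive correlation. A shared batch cannot be told apart from this choice. Blocking on these samples raised the JQ1 calls to 995 in male and 960 in female cells, which does not tell them apart either. In splits of the 12 libraries, 1 of 10 called as many genes in each of 4 comparisons, too few splits for a share under 0.05: 3503 (highest other 0), 1906 (655, male DMSO 1 with male JQ1 1 and 3), 2347 (1) and 4153 (1). For the difference of responses 1 of 100 did, 670 against 478. Chance is not excluded for it either, since libraries that are nearly duplicates cannot be exchanged and the fit of averaged samples called 0.

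Differences in peaks per sample ranged, without 1 sample, from -5260 to 1316 for sex, -3226 to 8981 for JQ1 in male and -2829 to -50.75 for JQ1 in female cells. Stricter peaks gave 96 for the last. Regions gained or lost between groups numbered 6968 for sex and 2715 and 3650 for JQ1 in male and female cells, and 7900 to 9849, 3293 to 6721 and 4523 to 5863 without 1 library (4525 without male DMSO 1, 6721 without male JQ1 2, 5845 without female DMSO 3, 5863 without female JQ1 2). Other splits of the same libraries gave up to 1154 regions for sex and 635 for JQ1 in female cells. For JQ1 in male cells, male DMSO 1 with male JQ1 1 and 3 against the rest gave 2263. Of the authors' sites 2387 of JQ1 in male and 8358 of JQ1 in female cells passed an FDR of 0.01, 8766 of the last had a log2 fold of at least 1, and without X and Y 24014, 4902 and 13460 remained. Fisher's exact test without matching called 5 lists for sex and 2 and 6 for JQ1 in male and female cells, and an FDR of 0.01 gave 0 for the last. Camera with an estimated correlation gave 0 lists for sex, and leaving out a sample 2 to 3 lists for sex and 0 to 1 for either JQ1 comparison. With 12 libraries, the replicate block and the block by the sample with fewer peaks fry called 24, 25 and 21 lists for sex, 1, 0 and 0 for JQ1 in male and 9, 8 and 4 for JQ1 in female cells. At an FDR of 0.01 the odds ratio at gene ends was 0.989 for sex, and that of female-higher with JQ1-lowered regions in female cells 1.16.

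Direction was reversed in 31 of 1113 values of the named genes checked. All 31 were of genes that had not passed, while the 1113 also include the values of genes that had. The groups of genes that had passed did not overlap, so leaving out a sample could not reverse them. Without 1 sample, the sex difference in log2 ranged from -0.0351 (without female DMSO 3) to 0.39 for Nf1 and from -0.25 to 0.0642 for Myc (0.0642 without female DMSO 1 and 2, 0.0385 without male DMSO 2 and 3). Scaling gave 0.0064 for Brd4 and 0.0249 for Myc. For JQ1 in male cells the ranges without 1 sample were -0.28 to 0.26 for Uty (0.20 without male DMSO 1, 0.26 without male JQ1 2), -0.0699 (without male JQ1 2) to 0.41 for Kdm5d, -0.53 to 0.0530 (without male DMSO 1) for Eif2s3y, -0.14 (without male JQ1 1 and 3) to 0.26 for Trp53, and -0.0775 to 0.0545 for Brd4 (0.0058 without male DMSO 2 and 3, 0.0545 without male JQ1 2). Stricter peaks gave 0.009 for Ddx3y and -0.46 for Kdm5d, a margin of 50 kb 0.0291 for Hexim1, and 12 separate libraries, with and without a block, 0.15 for Uty and 0.0048 for Brd4. For JQ1 in female cells the ranges were -0.22 to 0.20 for Xist (0.0284 without female DMSO 1 and 2, 0.20 without female JQ1 2), -0.0522 to 0.0201 (without female JQ1 1 and 3) for Hexim1 and -0.31 to 0.11 for Myc (0.058 without female DMSO 1 and 2, 0.11 without female JQ1 2). Xist also gave 0.0028 (2 kb), 0.25 (50 kb), 0.0451 (scaled) and 0.0458 (12 libraries, with and without a block), and Hexim1 0.0029 (50 kb) and 0.0450 (scaled).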

Other observations

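WNT, NOTCH and steroid hormone genes carried sites of both directions, and none of these lists passed on the authors' sites. On covered length camera called none of them, while fry called the WNT list in the sex comparison (limma fry adjusted p = 0.0103). The description of strong sites at gene ends was chosen after the result at gene ends had been seen.

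WNT genes split between the sexes. In the authors' deposited table sites in Wnt7b (log2 fold 4.26, chromosome 15, 85574797 to 85575397) and Wnt4 (2.50) were male-higher and sites in Dkk2 (-5.63) and Tcf7l2 (-3.91) female-higher. Over 26 WNT genes, 16 had a male-higher site against 13.6 in random lists and 15 a female-higher one against 12.9 (adjusted p = 1 for both). JQ1 raised sites of Wnt7b in male (2.09, chromosome 15, 85523396 to 85523996) and in female cells (3.19, chromosome 15, 85568604 to 85569204).

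NOTCH genes had male-higher sites at 9 of 14 members against 6.42 in random lists (adjusted p = 0.682) and female-higher sites at 7 against 6.15, among them sites near Rbpj (-4.52) and Nrarp (-2.76). JQ1 in female cells raised sites near Notch3 (4.99, chromosome 17, 32106442 to 32107042) and Notch2 (3.74, chromosome 3, 97993027 to 97993627). Of 11 sex hormone receptor and steroid genes, 5 had a female-higher site against 3.88 and 3 a male-higher one against 4.03 (adjusted p = 1 for both). Esr1, an estrogen receptor gene, had a female-higher site (-4.48, chromosome 10, 4646608 to 4647208), as did Ncoa3 (-5.41). A site near Fkbp5 had a log2 concentration of 7.37 in female cells and the lowest listed value, -0.04, in male cells. A site in Ncoa1 (chromosome 12, 4356864 to 4357464) was lowered by JQ1 in both sexes, from 5.79 to the lowest listed value of -0.15 in male cells and by a log2 fold of -4.12 in female cells.

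A site in Cdkn1a, a p53 target (chromosome 17, 29091340 to 29091940), was female-higher (-2.34) and lowered by JQ1 in female cells (-2.21) and in male cells, from 3.98 to the lowest listed value, -0.15. Sites near the stem cell genes Sox2 (3.43) and Sox1 (2.65) were male-higher and a site in Pax6 (-1.86) female-higher. Glycolysis genes had a female-higher site at 3 of 22 members against 7.71 in random lists (permutation p = 0.0222, adjusted p = 0.319).

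Among sites above the 75 percent quantile of concentration, those lowered by JQ1 lay within 1 kb of a gene end in 71.3% of 1164 in female and 20.5% of 552 in male cells, against 11.3% of 2266 and 3.62% of 691 raised sites.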
